A study of Mus musculus with 4 samples.

How the data were processed

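RNA from testes of adult male mice was sequenced, with 2 libraries from wild-type (WT) animals and 2 from Fam46c knockout (KO) animals. Per the labels, the mice were of a DBA/C57 F1 background, total RNA was isolated with TRIzol, libraries followed Illumina protocols, and the HiSeq X10 was the sequencer. The labels do not say whether the libraries of a group came from separate animals, so all p-values measure only the spread between these 4 libraries, which may be technical. No litter, sequencing batch or date is given in the sources used here.

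The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), per the file headers. There is 1 table per library, with gene symbols in its first column. TopHat2 2.0.6, Cufflinks 2.0.2, Cuffdiff and the mm9 mouse genome build are named, without role or order, per the submitters' processing notes. A version of Cuffdiff, the gene annotation, the strand setting, any filter and the handling of fragments that map to several places are not given in the sources used here. Cufflinks estimates how fragments are shared among overlapping or near-identical transcripts, so values of short genes, repeated genes and close paralogs are less certain than those of unique genes. Each table held 23021 rows and 22552 symbols in the same set but in a different row order. The 259 symbols that stood on more than 1 row (728 rows) had their FPKM summed. An exact 0 in these tables is not proof of absence: 4 of 83 ribosomal protein symbols, among them Rps12, Rps28 and Rpl12, were at 0 in all 4 libraries, as were 104 of 105 small nucleolar RNA symbols. A gene at 0 is therefore described as listed at 0, with each library's value and no fold.

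Total FPKM was 498299 and 497141 in WT replicates 1 and 2, and 528756 and 489702 in KO replicates 1 and 2. FPKM carry no read counts, but the low values keep the steps made by whole fragments. Among genes above 0.001 and under 0.1 FPKM, ratios to WT replicate 2 gathered at 1 value and at its whole-number multiples and fractions. Of these ratios, 81.2% to 83.1% lay within 1% of such a value, against 4.3% to 5% after every ratio was shifted by 5%. The position of this value gives depths of 0.901, 0.781 and 0.905 of WT replicate 2 for WT replicate 1, KO replicate 1 and KO replicate 2. Lengths of genes with a single GENCODE M21 transcript put WT replicate 2 at about 20600000 to 23000000 fragments, depending on whether 0 or 200 bases are taken off each length. This is a rough value, because the annotation behind the deposited FPKM is not known. At about 18000000 fragments, the shallowest library, KO replicate 1, would hold about 18 fragments for a 1 kb transcript at 1 FPKM, a counting error of 23.6%. At 5 FPKM it would hold about 90, an error of 10.5%. These errors cover counting only.

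Values were analysed as log2(FPKM + 1) for the 12258 symbols with a mean of at least 1 FPKM over the 4 libraries. KO was compared with WT in limma 3.58.1 under R 4.3.3, with a linear model per gene and variances moderated across genes with an intensity trend. P-values were two-sided with Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. There were 2 residual degrees of freedom and 9.48 prior degrees of freedom. A log2 fold change is on the scale of FPKM + 1, which understates the change of low genes. A second count, with no test, took genes at least 2-fold apart in the mean of FPKM + 1 whose libraries of one group all lay above both of the other. Chance alone puts 33.3% of genes apart in either direction with 2 against 2 libraries, so the same count was made in the other 2 ways of pairing the 4 libraries.

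Before the data were examined, 22 gene lists were fixed. Germ cell lists were poly(A) polymerases, sperm head-tail coupling, outer dense fibre and fibrous sheath, axoneme, acrosome, chromatin condensation, CatSper and motility, spermatid regulators, meiosis and spermatogonia. Lists of other cells were Sertoli, Leydig, peritubular myoid and endothelial, macrophage and antigen presentation, blood and epididymis. General lists were endoplasmic reticulum folding, apoptosis, immediate early genes, replication-dependent histones, ribosomal proteins and mitochondrially encoded genes. Lists with at least 5 tested members were compared with all other genes by limma's camera with its preset inter-gene correlation of 0.01, and again with an estimated correlation. Fry, also from limma, tested whether the genes of a list moved one way on balance. With 2 libraries per group, fry and camera with an estimated correlation have little power. A list that they do not call is therefore not shown to be unchanged. The genes to be named were also set in advance. They were the Fam46 family and, in each direction, the 12 called genes with the largest fold change and non-overlapping groups, filled up with genes of smallest p where fewer passed. From each list, up to 4 tested members of smallest p were added. One gene that this rule names is not reported here. Genes named outside this rule were chosen after their values were seen, as were Rps12, Rps28 and Rpl12 above, and the report says so beside them, except for Prm1, Prm2 and Tnp2, taken as the sperm chromatin genes of highest FPKM with Tnp1.

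The gene test was tried on simulated data for the 12258 genes, with 100 genes changed 2-fold and 100 changed 4-fold. With gene variances drawn from the fitted prior it recovered 72% of the 2-fold and 95% of the 4-fold changes, with 10 false calls among the unchanged genes. With the moderated variance estimates as the true variances it recovered 87% and 100%, with 27 false calls. Many changed genes let an adjusted p under 0.05 be reached at a larger unadjusted p. Recovery may therefore be lower than these shares where few genes change. In simulated data without change, camera called 0 of 19 lists. The simulated noise was independent between genes, so this count does not cover lists whose members vary together. Alternatives tried were other pseudocounts, other filters, 3 ways of rescaling the libraries, no variance trend, robust variance moderation, a block for the replicate number and leaving out each library in turn. Restricting the tables to symbols listed once, and the Leydig list to fewer members, were chosen after the data were seen. Gene order along chromosomes and current gene names came from the RefSeq table of GRCm38.p6, in which 12148 of the 12258 tested symbols were found. No coordinates are given because the deposited values rest on mm9. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for these steps, and matplotlib 3.10.9 for the figures.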

Results

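Transcript levels of adult testes were measured in 2 WT and 2 Fam46c KO libraries. FAM46C is a noncanonical poly(A) polymerase, an enzyme that adds adenosine tails to RNA. The stated purpose of the comparison was to find testis genes whose level depends on it. Between 17833 and 18076 of the 22552 symbols were above 0 in a library. The sperm chromatin genes Prm1, Prm2, Tnp1 and Tnp2 together took 9.04% and 12% of the total FPKM in the WT libraries and 12.5% and 10.8% in the KO libraries. Across genes, log2 values of any 2 libraries correlated at 0.988 to 0.992, and both pairs within a group lay inside the range of pairs across groups. The SD of the log2 difference was 0.25 between the WT libraries, 0.26 between the KO libraries and 0.24 to 0.29 between libraries of different groups.

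The targeted transcript itself was not lower in the KO libraries by more than the spread. Fam46c stood at 236 FPKM in WT replicate 1 and 134 in WT replicate 2, against 131 and 129.9 in the KO replicates. This is a log2 fold change of -0.45 (SE 0.21, limma, Benjamini-Hochberg adjusted p = 1). The value rested on WT replicate 1: without it the log2 fold change was -0.04, and without WT replicate 2 it was -0.85. The part of the gene that was mutated is not given in the sources used here, so this transcript level does not check the labels. Of its relatives, Fam46b was at 20.9 ± 1.37 FPKM in WT and 21.6 ± 5.43 in KO, and Fam46d at 13.1 ± 2.58 and 11.0 ± 0.885 (SD, n = 2 each, limma adjusted p = 1 for both). Fam46a stayed between 0.114 and 0.223 FPKM in all 4 libraries and was not tested. Of the 13 tested poly(A) polymerase genes, which include Papd4 and Zcchc11, limma called 0, and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were also 0 (camera adjusted p = 0.499).

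Few transcripts were called different between the Fam46c KO and WT libraries, and 1 of them was Insl3, which encodes an insulin-like hormone made by Leydig cells. Insl3 fell from 1118 ± 25.7 FPKM in WT to 284 ± 134 in KO (SD, n = 2 each). Its log2 fold change was -2.06 (SE 0.24, limma adjusted p = 0.00507). The globin genes Hba-a1 and Beta-s, which encode the oxygen carrier of red blood cells, fell from 21.0 ± 1.66 to 0.657 ± 0.551 FPKM and from 13.4 ± 2.76 to 1.34 ± 0.0574 FPKM. Their log2 fold changes were -3.77 (SE 0.21) and -2.61 (SE 0.17) with limma adjusted p of 3.82e-06 and 1.34e-05. Lcn2, a lipocalin that binds iron carriers (148 ± 36.8 to 52.6 ± 20.2 FPKM), and Apoc1, an apolipoprotein (38.2 ± 8.94 to 15.0 ± 2.97), also fell. So did Fxyd1, a regulator of the sodium pump (28.2 ± 1.28 to 11.0 ± 3.83), and the chemokine Ccl8 (4.06 ± 0.426 to 1.18 ± 0.386). Their log2 fold changes were -1.51, -1.29, -1.32 and -1.22, with limma adjusted p of 0.0308, 0.0197, 0.0219 and 0.0201. Abra, which encodes an actin-binding protein, rose from 0.0304 and 0.0821 FPKM in the WT libraries to 1.79 and 3.39 in the KO libraries (log2 fold change 1.73, SE 0.21, limma adjusted p = 0.00576). The Insl3 call ended after median scaling (log2 fold change -2.05, limma adjusted p = 0.0771), after quantile normalization (-2.10, 0.172) and with no filter or robust variance (adjusted p = 1 for both), and with no filter limma called 2 genes in all, Snora81 and Amd1. Lcn2, Apoc1, Fxyd1, Ccl8 and Abra lost their calls under all 3 rescalings. Their limma adjusted p was 0.0758 to 0.186 after median scaling, 0.213 to 0.494 after quantile normalization and 0.0731 to 0.0983 after total scaling. Their log2 fold changes stayed at -1.20 or below and, for Abra, at 1.72 or above. Lcn2 also lost its call with no variance trend (limma adjusted p = 0.0822), and both Lcn2 and Fxyd1 with robust variance (0.0677 for Fxyd1).

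The other called genes were Snora81, Rn4.5s, Amd1, Hist1h4c, 1700016L21Rik and Gm5416. Snora81, a small nucleolar RNA of 164 bases, lies within Eif4a2 in GRCm38.p6. It was at 428 and 419 FPKM in the WT libraries and listed at 0 in both KO libraries (limma adjusted p = 4.48e-12). The other 104 small nucleolar RNA symbols were listed at 0 in all 4 libraries. Eif4a2 itself, looked up after the values were seen, was at 48.0 and 46.8 FPKM in WT and 46.9 and 56.9 in KO. Rn4.5s, a small RNA of 174 bases, has a symbol on more than 1 row. It was listed at 0 in both WT libraries and at 111 and 352 FPKM in the KO libraries (limma adjusted p = 1.33e-06). How fragments were assigned to Snora81 and Rn4.5s was not tested. Amd1, which encodes the S-adenosylmethionine decarboxylase of polyamine synthesis, fell from 5.20 and 4.69 FPKM to 0.00192 and 0.00164 (log2 fold change -2.57, SE 0.16, limma adjusted p = 9.37e-06). The sum of Amd1 and its near copy Amd2 was 13.4 and 11.5 FPKM in WT and 12.3 and 12.3 in KO. The histone H4 gene Hist1h4c fell from 5.51 and 3.75 FPKM to 0.0494 and 0.131 (log2 fold change -2.35, SE 0.19, limma adjusted p = 8.42e-05). The sum over 11 Hist1h4 genes was 94.3 and 61.7 FPKM in WT and 58.3 and 87.9 in KO. 1700016L21Rik was at 3.39 and 1.52 FPKM in WT and listed at 0 in both KO libraries (limma adjusted p = 0.0126). Its call ended with a pseudocount of 5 (limma adjusted p = 0.0575) and with robust variance (0.0505). It also ended after median, quantile and total scaling (0.0771, 0.258 and 0.0758). Gm5416, named Csta3 in GRCm38.p6, was at 0 and 0.938 FPKM in WT and at 3.5 and 4.32 in KO (limma adjusted p = 0.0197). The Gm5416 call ended with a pseudocount of 0.1 (limma adjusted p = 0.279) and with robust variance (0.369). It also ended after median, quantile and total scaling (0.186, 0.494 and 0.157).

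In all, 3 genes rose and 11 fell among 12258 tested with limma at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 248 genes, fewer than the 612.9 that make up 5% of those tested. The other 2 ways of pairing the libraries gave 804 and 984 genes at that level but 0 calls each. At least 2-fold apart without overlap were 30 genes, 5 higher and 25 lower, against totals over both directions of 6 and 10 in the other 2 pairings. Among the genes of smallest p that did not pass was Ly6e, with 11.2 ± 0.858 FPKM in WT and 5.36 ± 0.899 in KO (limma adjusted p = 0.0695). With higher KO values they were Ndufb4, Apoa2, Amd2, Rps23, Defb41, Gm7334, 1700010J16Rik, 1700072B07Rik and D330023K18Rik (limma adjusted p from 0.0948 to 0.703). Calls of Snora81, Hba-a1, Beta-s, Amd1, Hist1h4c and Rn4.5s passed with any 1 library left out, although Rn4.5s missed the threshold with robust variance (limma adjusted p = 1) and with no filter (0.0875). Insl3 missed the threshold without WT replicate 1 (limma adjusted p = 0.0847) or WT replicate 2 (0.0843), as did Lcn2 (0.45 and 0.0595), Fxyd1 (0.236 and 0.138) and Ccl8 (0.174 and 0.0699), Apoc1 without WT replicate 2 (0.162) and Abra without WT replicate 1 (0.0573). Without KO replicate 2, limma adjusted p was 0.131 for Lcn2, 0.0913 for Fxyd1, 0.362 for Ccl8, 0.182 for Apoc1, 0.322 for Gm5416 and 0.151 for 1700016L21Rik, and without KO replicate 1 it was 0.0775 for Gm5416 and 0.079 for 1700016L21Rik.

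**Figure D1:**
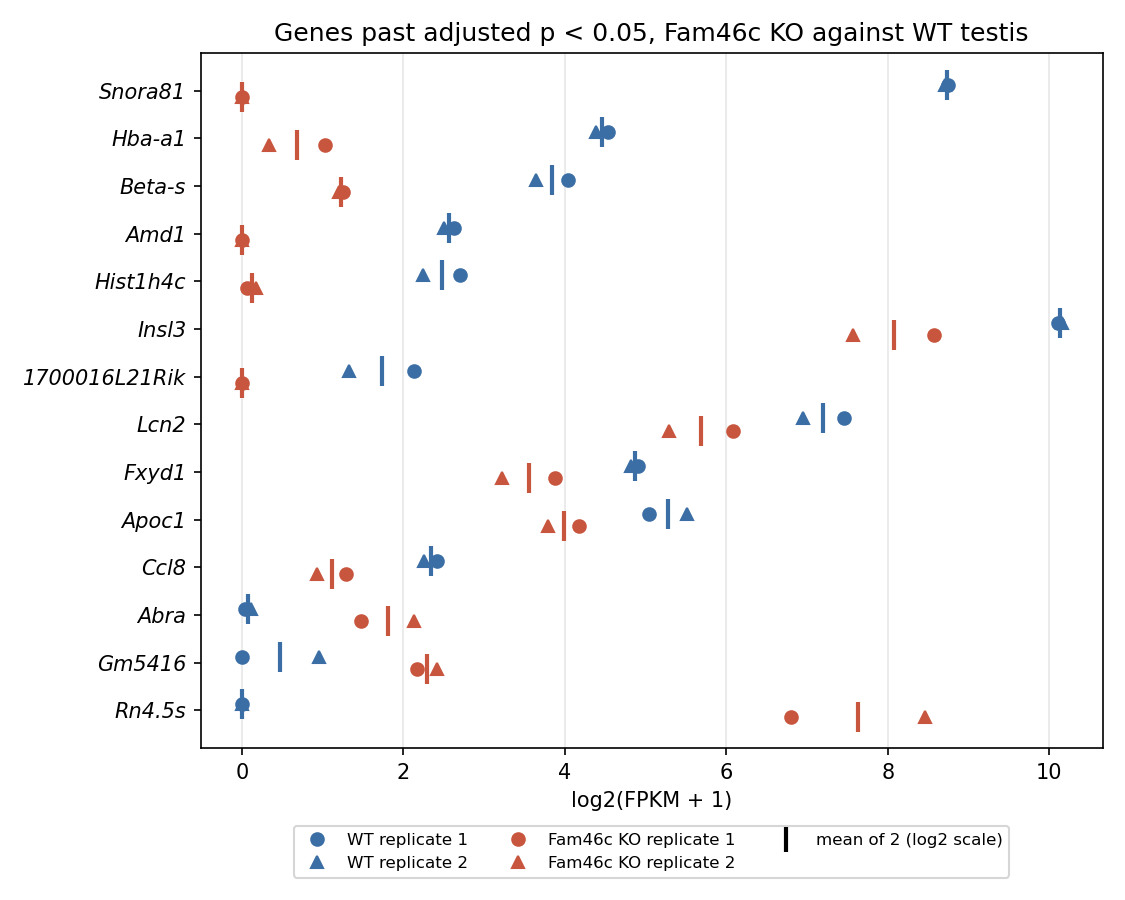
Level of each called gene as log2(FPKM + 1), with 1 symbol per library (WT in blue, Fam46c KO in red, circles for replicate 1 and triangles for replicate 2) and a bar at the mean of 2 libraries. Insl3 lies between 1100 and 1136 FPKM in WT and at 379 and 189 FPKM in KO, and Snora81 and Rn4.5s are listed at 0 in both libraries of 1 group.

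The study concerns the attachment of the sperm head to its flagellum, and the transcripts of the structures involved showed no called difference between the genotypes. Of 17 tested head-tail coupling genes limma called 0, with a median log2 fold change of -0.01 and a mean of 0.01 (camera adjusted p = 0.972). Odf1, a component of the outer dense fibres that also lies at the sperm neck, was at 1454 ± 85.1 FPKM in WT and 1231 ± 128 in KO, a log2 fold change of -0.24 (SE 0.14, limma adjusted p = 1). Spag4, a SUN-domain protein of the spermatid nuclear envelope, was at 148 ± 7.28 and 167 ± 14.3 FPKM, and Ccdc46 and the centrosomal Azi1 had log2 fold changes of 0.18 and 0.18 (limma adjusted p = 1 for each). The 19 outer dense fibre and fibrous sheath genes had a median of 0.00 and a mean of -0.01, with Gk2 at -0.11 and Ropn1 at 0.14. The 27 axoneme genes had a median of -0.03, with Meig1 at 0.22 and Ccdc39 at 0.17. The 27 acrosome genes had a median of 0.00 and a mean of -0.01, with Spam1 at -0.22 and Zpbp2 at 0.11. The 21 CatSper and motility genes had a median of -0.01, with Smcp, a protein of the sperm mitochondrial capsule, at -0.22 and Catsper3 at 0.14. In each of these 5 lists limma called 0 genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, with a camera adjusted p of 0.972.

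Germ cell genes of earlier and later stages gave the same count. The 16 chromatin condensation genes had a median log2 fold change of 0.08, with Tnp1, a transition protein that replaces histones, at 0.38 and H2afb1 at 0.34 (camera adjusted p = 0.499). The 27 spermatid regulators, with the kinase gene Tssk3 at -0.13 and Tdrd6 at -0.14, had a median of 0.00 (camera adjusted p = 0.972). The 31 meiotic genes, with the break-forming Spo11 at -0.24 and Hormad2 at -0.28, had a median of -0.05 (camera adjusted p = 0.295), and the 15 spermatogonial genes, with Uchl1 at 0.14 and Sohlh1 at 0.31, one of -0.04 and a mean of 0.02 (camera adjusted p = 0.972). The chromatin list was called with a mean of at least 5 FPKM (camera adjusted p = 0.0306) and the meiotic list without KO replicate 2 (0.0196), but with an estimated correlation over all 4 libraries p was 0.505 and 0.595. In each of these 4 lists the limma count was 0 over all genes and 0 adjusted over the list alone, and H2afb1 was the 1 gene with an unadjusted p under 0.05. In the simulated data a 2-fold change was recovered in 72% or 87% of genes, depending on the variances used, and smaller changes were not simulated. Smaller changes in single genes of these lists may therefore have gone undetected with 2 libraries per group.

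**Figure D2:**
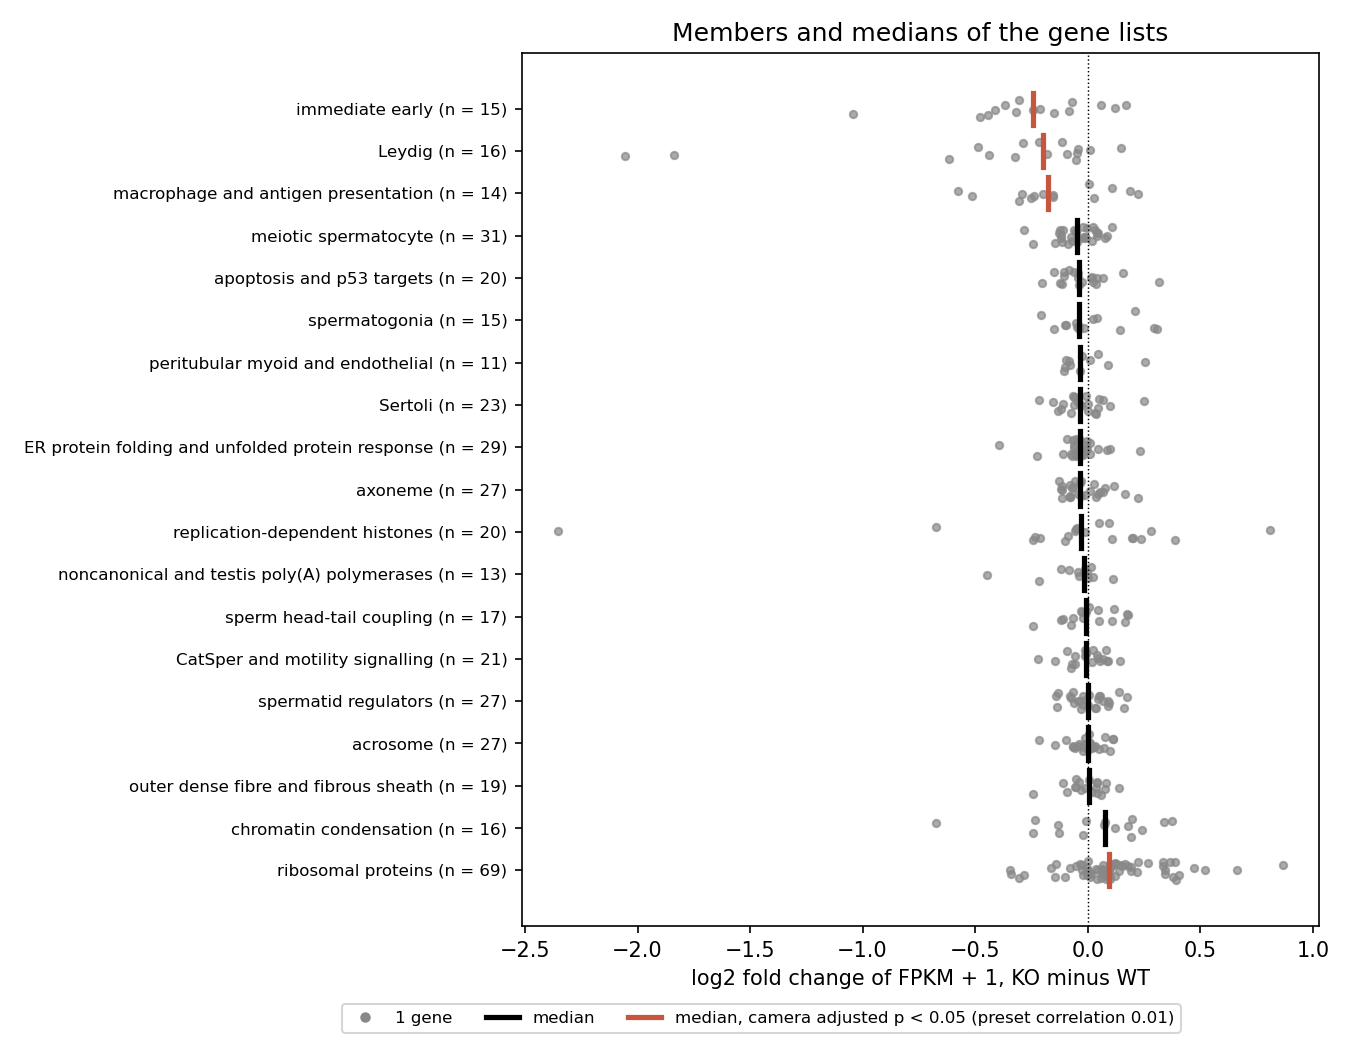
Log2 fold changes of FPKM + 1 (KO minus WT) for the tested members of each gene list, with 1 point per gene and a bar at the median, red where camera with the preset correlation gave an adjusted p under 0.05. Medians of the sperm structure and chromatin lists lie between -0.03 and 0.08, and the Leydig list has 2 members, Insl3 and Hsd3b6, far below the rest.

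Among the somatic cells of the testis, the Leydig cell list stood lower in KO, with 2 of its 16 tested genes far below the others. Insl3 was the 1 member called over all genes, and Insl3 and Hsd3b6, a steroid dehydrogenase of adult Leydig cells, were the 2 that passed when adjusted over the list alone. Hsd3b6 was at 4.94 and 17.1 FPKM in WT and at 2.35 and 1.5 in KO (log2 fold change -1.84, SE 0.38, limma adjusted p over all genes = 0.203). Adh1 was at 3.23 and 4.29 FPKM in WT and 2.84 and 1.48 in KO (log2 fold change -0.62, limma adjusted p = 1). Of the 16 genes, 14 had a negative log2 fold change and 3, Insl3, Hsd3b6 and Adh1, had an unadjusted p under 0.05. The list median was -0.20 (limma camera adjusted p = 5.04e-07), but with an estimated correlation p was 0.154 before and 0.989 after adjustment. The other members named here, except Hsd17b3, were chosen after their values were seen. The steroidogenic genes Star, Cyp11a1, Cyp17a1 and Hsd17b3 were low in KO replicate 2 and not in KO replicate 1. Cyp17a1 stood at 77.4 and 128 FPKM in WT and at 129 and 56.4 in KO, and Star at 7.75 and 13 in WT and 12.3 and 4.0 in KO. Hsd3b1, Scarb1 and Fdx1 had log2 fold changes of 0.15, 0.01 and -0.05. Without KO replicate 2 the camera adjusted p of the list was 0.605, and without Insl3 and Hsd3b6, a choice made after the data were seen, it was 0.00516.

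**Figure D3:**
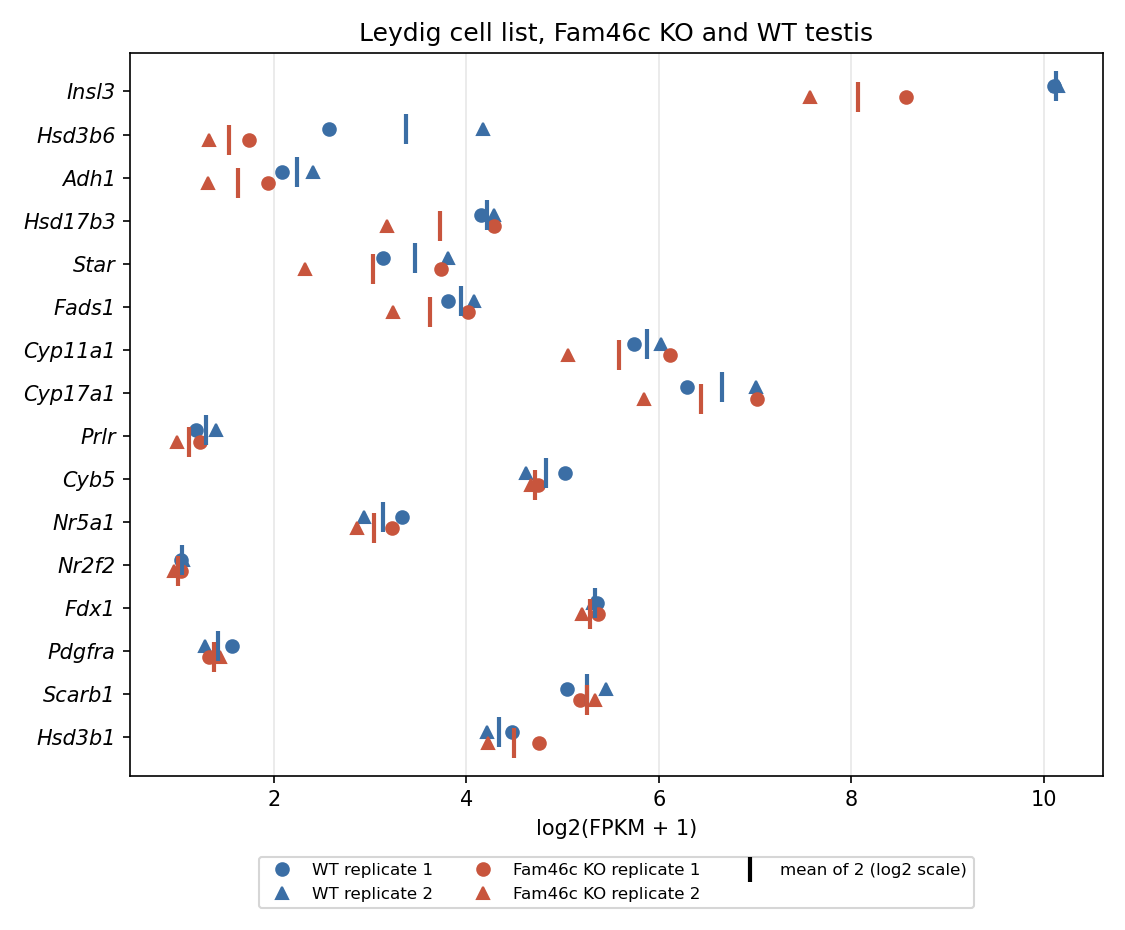
Level of the 16 tested Leydig list genes as log2(FPKM + 1), with 1 symbol per library (WT in blue, Fam46c KO in red) and a bar at the mean of 2 libraries. Insl3 and Hsd3b6 lie lower in both KO libraries, while Star, Cyp11a1, Cyp17a1 and Hsd17b3 are low in KO replicate 2 (triangles) and within or near the WT range in KO replicate 1 (circles).

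Genes of Sertoli cells, the vessel and tubule wall and macrophages showed no called member. Sertoli cell genes (23 tested, with Gata4 at -0.22 and Amh at 0.25) had a median log2 fold change of -0.03 (camera adjusted p = 0.882, and 0.0136 without WT replicate 2). With an estimated correlation over all 4 libraries p was 0.82 for this list. The median was -0.03 for peritubular myoid and endothelial genes (11 tested, with Cnn1 at 0.26, camera adjusted p = 0.972). The macrophage and antigen presentation list had a median of -0.18 over 14 genes, with the class II genes H2-Aa at -0.57 and Cd74 at -0.51 and with Aif1 at 0.22 (camera adjusted p = 0.0405, and p = 0.155 with an estimated correlation). Its call ended without WT replicate 1 (camera adjusted p = 0.411), KO replicate 1 (0.0734) or KO replicate 2 (0.771). In these 3 lists limma called 0 genes, and 0 adjusted over the list alone, and H2-Aa was the 1 gene with an unadjusted p under 0.05. Of the blood genes 3 were tested, too few for camera, and Hba-a1 was called. Hbb-b2 was at 3.94 and 1.76 FPKM in WT and 0.600 and 0.417 in KO (limma adjusted p = 0.121), and passed with Hba-a1 when adjusted over the list alone, for a count of 2. Alas2, an enzyme of haem synthesis, was at 9.03 and 7.62 in WT and 9.61 and 5.5 in KO. The Hba-a1 symbol stood on more than 1 row. Of 21 epididymal genes, a check for attached epididymis, only Cst8, Rnase10 and Spink8 were tested, with log2 fold changes of 0.24, 0.00 and -0.14. Cst8 was at 368 and 435 FPKM in WT and 473 and 474 in KO. Rnase10 and Spink8 lay between 0.625 and 3.75 FPKM, so the 3 genes do not give 1 picture of epididymal tissue. Limma gave 0 calls there, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05.

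Among the lists of general cell state, 12 of 15 immediate early genes had a negative and 52 of 69 ribosomal protein genes a positive log2 fold change, and limma called 0 genes in both lists. The 15 immediate early genes, transcription factors and feedback regulators induced within minutes of a stimulus, had a median of -0.24, with Fos at -1.04, Egr1 at -0.48, Btg2 at -0.44 and Jun at -0.31 (limma camera adjusted p = 2e-05, and p = 0.212 with an estimated correlation), and 0 passed when adjusted over the list alone. At an unadjusted p under 0.05 there were 3 of them, Fos, Egr1 and Btg2. Fos was at 3.41 FPKM in WT replicate 1 and 0.449 in WT replicate 2, against 0.402 and 0.0744 in KO. The camera adjusted p of the list was 0.197 without WT replicate 1 and 0.281 without KO replicate 1. The 69 ribosomal protein genes had a median of 0.10, with Rpl35 at 0.36 and Rpl37a at 0.40 and, chosen after their values were seen, Rpl10 at -0.35 and Rpl24 at -0.34 among the 17 negative ones (limma camera adjusted p = 5.08e-06, and p = 0.307 with an estimated correlation). Of these genes 6 had an unadjusted p under 0.05, and 1, Rps23 (0.705 and 1.28 FPKM in WT, 2.43 and 2.76 in KO), passed when adjusted over the list alone. This list gave a camera adjusted p of 0.0931 without WT replicate 2 and 0.912 without KO replicate 1. The 29 genes of endoplasmic reticulum folding, with P4hb at -0.22 and Calr3 at 0.23, had a median of -0.03 (camera adjusted p = 0.499). The 20 genes of apoptosis, with Bax at 0.32 and Ccng1 at -0.20, had a median of -0.04 (camera adjusted p = 0.972). Limma called 0 genes in both lists, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Of 20 replication-dependent histone genes, Hist1h4c was called. Hist1h2bj, at 0.767 and 1.38 FPKM in WT and 3.47 and 1.9 in KO, passed with it when adjusted over the list alone, for a count of 2 (list median -0.03, camera adjusted p = 0.972). Mitochondrially encoded genes were not analysed here. Of the 4 camera calls with the preset correlation, 0 held with an estimated correlation, and fry gave 0. Both of these tests have little power with 2 libraries per group, so the lost calls do not show that the 4 lists are unchanged.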

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

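Restricting the tables to symbols listed once was chosen after the data were seen, as was shortening the Leydig list. The Fam46c difference and the head-tail coupling list stayed on the same side of the threshold under every alternative tried, while the count of called genes moved with several settings. Against 3 higher and 11 lower genes (limma, Benjamini-Hochberg), the counts were 0 and 2 with no filter, 1 and 8 with a mean of at least 5 FPKM, 1 and 5 with median scaling, 1 and 5 with quantile normalization, 1 and 6 with total scaling and 1 and 7 with robust variance. Leaving out 1 library, which leaves a lone sample assumed to vary like the other group, gave 2 to 5 higher and 7 to 18 lower genes. Amd1 and Snora81 were called under every alternative in which they were tested, and Hba-a1, Beta-s and Hist1h4c in all of theirs but the one without a filter. Hba-a1 and Rn4.5s drop out when only symbols listed once are used. All alternatives start from the same FPKM, so none of them tests how fragments were assigned to short genes such as Snora81 or to near copies such as Amd1. Over the alternatives the limma adjusted p of Insl3 ranged from 2.5e-46 with the replicate block, where the variance was pooled fully across genes on 1 residual degree of freedom, to 1 with no filter or robust variance. Genes at least 2-fold apart numbered 11 higher with a pseudocount of 0.1, 1 higher and 11 lower with one of 5, 2 higher and 12 lower with a mean of at least 5 FPKM, and 7 to 16 higher and 21 to 44 lower with 1 library left out. Replicate numbers do not pair the samples as far as the data show: the difference between replicates 1 and 2 correlated at -0.03 across genes between WT and KO. A block for the replicate number gave 18 higher and 50 lower genes and kept all 14. Of the list calls (limma camera adjusted p), the macrophage list missed the threshold with no filter (0.086), with a mean of at least 5 FPKM (0.24), with quantile normalization (0.103), with total scaling (0.151) and with the replicate block (0.0822), and the immediate early list with a mean of at least 5 FPKM (0.833). With an estimated correlation the adjusted p was 0.989, and with fry 0.967, for each of the 4 called lists. The camera value of 0.989 was the same for every list tested, so that setting did not tell lists apart. With 1 library left out the adjusted p ranged from 5.93e-13 to 0.605 for the Leydig list, 0.0136 to 0.771 for the macrophage list, 2.75e-08 to 0.281 for the immediate early list and 5.06e-12 to 0.912 for the ribosomal list. Without Insl3 the Leydig list gave 0.000102, and without Insl3 and Hsd3b6 0.00516. Of all other values, 1603 stayed on their side of the threshold, most of them values not called in the main fit. A further 62 calls ended, all of them of the 14 called genes, of which only Amd1 and Snora81 lost none. Another 20 calls were gained, with 0 reversals. Among those gained were camera calls of the chromatin list with a mean of at least 5 FPKM (adjusted p = 0.0306), the Sertoli list without WT replicate 2 (0.0136) and the meiotic list without KO replicate 2 (0.0196), none of which was called with an estimated correlation over all 4 libraries (adjusted p = 0.989). Apart from fewer genes or libraries entering the fit, the cause was not tested. Low genes are limited by depth, with a counting error of about 23.6% at 1 FPKM on 1 kb in the shallowest library.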

Other observations

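The genes of this paragraph were chosen after their values were seen, from those at least 2-fold lower in KO without overlap that did not pass the test, and Klk1b8 was added as a neighbour. Agt, which encodes angiotensinogen, was at 57.1 and 64.4 FPKM in WT and 37.4 and 18.2 in KO (limma adjusted p = 0.203). In the Klk1b cluster of kallikrein-related proteases, Klk1b21 was at 16.9 and 23.9 FPKM in WT and 9.80 and 3.33 in KO, and Klk1b24 at 15.4 and 19.8 in WT and 9.93 and 2.71 in KO, with Klk1b22 and Klk1b16 in the same direction. Klk1b8 was at 52.6 and 66.9 FPKM in WT and 80.5 and 67.7 in KO, and the sum over 14 Klk1b genes was 135 and 189 in WT and 160 and 127 in KO. Others were Gpx3, a glutathione peroxidase (9.32 and 2.80 FPKM in WT, 1.46 and 1.07 in KO), Lrg1 (2.80 and 2.37, against 1.15 and 0.208) and the complement gene C3 (4.35 and 0.827, against 0.713 and 0.541). Tcte3, a dynein light chain gene of the testis, was at 1039 and 1709 FPKM in WT and 647 and 664 in KO (log2 fold change -1.02, limma adjusted p = 0.16). In several of these genes KO replicate 2 was the lowest library, as it was for Star and Cyp17a1.

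All tests below were chosen after the result was seen, except the one on the genes next to Fam46c. The first pattern is the lower Insl3 in KO. A smaller number of Leydig cells as the whole cause was set against the other 15 measured Leydig list genes. Their median log2 fold change was -0.1791 (SD 0.47) against -2.06 for Insl3, on a scale that understates changes of low genes. Members that other testis cells may also express can hold this median up, and Hsd3b6 had -1.84, so the median alone does not decide. It also hides a split between the KO libraries. Cyp11a1 and Cyp17a1, chosen after their values were seen, were at 68.6 and 129 FPKM in KO replicate 1. In WT they were at 52.5 and 63.8 FPKM and at 77.4 and 128 FPKM. With Insl3 at 379 FPKM in KO replicate 1, this argues against fewer Leydig cells as the whole cause in that library. In KO replicate 2 Cyp11a1 and Cyp17a1 were at 32.4 and 56.4 FPKM, so fewer Leydig cells as part of the cause there stays open. A wrong scale of the KO libraries is argued against by the median of all tested genes, -0.0065. That measure replaced a first criterion, that Insl3 keep its call under all 3 rescalings, after that one was seen not to be met. The call ended after median scaling (log2 fold change -2.05, SE 0.27, limma adjusted p = 0.0771) and quantile normalization (-2.10, SE 0.26, 0.172), against -2.06 (SE 0.24) without rescaling, while the difference hardly moved. Prior degrees of freedom fell from 9.48 to 6.25 and 4.51. After total scaling they fell to 6.58, but the SE was 0.23 and the call was kept (log2 fold change -2.09, limma adjusted p = 0.0203). Among the 3 rescalings, the call was thus lost where the SE rose as the prior degrees of freedom fell. Why the SE rose was not tested. An effect of genotype on Insl3 and a difference between these animals that is unrelated to genotype both stay open, untested. So does a difference in how the WT and KO libraries were prepared or sequenced, because no batch is given. The same 3 possibilities stay open for the other called genes.

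The second pattern is the lower globin level, with a sum over 5 globin genes of 41.5 and 33.1 FPKM in WT and 3.03 and 3.23 in KO. Less blood left in the KO tissue would lower other genes of red blood cells too. Alas2, the 1 tested blood list gene other than globins, had a log2 fold change of -0.1631, and because a single gene that testis cells may also express decides nothing, this explanation stays open. The beta-globin cluster differs between DBA and C57 strains, but that haplotype as the whole cause is argued against by the summed alpha-globin level on another chromosome, with a log2 ratio of -4.0389. An effect of the genotype on blood content was not tested and stays open.

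The third pattern is the loss of FPKM from Amd1 and Hist1h4c, which have near-identical copies. For Amd1, assignment of the same fragments to Amd2 is consistent with a log2 ratio of -0.0138 for the sum of both genes, within the 0.22 between the WT libraries, and Amd2 was at 8.17 and 6.81 FPKM in WT and 12.3 and 12.3 in KO. For Hist1h4c, assignment to other H4 genes is consistent with a log2 ratio of -0.094 for the sum of 11 Hist1h4 genes, within the 0.61 between the WT libraries, a spread too wide to exclude a loss of the few FPKM of Hist1h4c. A real change of either gene with an opposite change in its copies stays open, because fragments were not analysed here.

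The last test asked whether a DBA or C57 segment carried along with the Fam46c mutation may have altered its neighbours. The 50 tested genes on each side of Fam46c along its chromosome in GRCm38.p6 had a median absolute log2 fold change of 0.0729, against a 95th percentile of 0.0909 and a median of 0.0699 in 10000 random windows of 100 neighbouring genes, and 0 of them were called. The neighbours as a set thus did not stand out from other windows. A median over them cannot show a change in a few genes, so a segment that altered only some neighbours stays open. Single genes were not examined for strain variants.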
